A study of Mus musculus with 2 samples.

How the data were processed

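RNA of the hippocampus of heterozygous female 5xFAD mice was sequenced with long reads in 2 libraries, each from a biosample of its own and labelled as biological replicates 1 and 2 of one experiment. Both labels name the same donor record, which describes the strain. All p-values compare these 2 libraries, and none measures a spread between animals. Unless a coefficient of variation is named, they are set against counting noise only. That coefficient was estimated from the same 2 libraries, so it holds every kind of difference between them. Per the labels, SIRV and Ambion mix 1 (ERCC) spike-ins were added. Per the notes deposited with the files, reads were aligned to the mm10 assembly with the GENCODE M21 annotation and the spike-in sequences, and 1 filtered alignment file was used per library. The source field of the deposited annotations names TALON as the builder of the transcript models. Its version, its read filters and the aligner are not given in the sources used here. The deposited values are counts, whole numbers of reads per transcript model without normalization, and models with 0 reads are not listed. The other values per model in the deposited files are its number of exons, its length and its class.

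Libraries held 1862373 and 1704633 reads in 199925 and 233322 models, of which 63.9% and 64.1% had 1 read. The median length of annotated models, weighted by reads, was 2580 and 2597 nucleotides, with 5% of reads below 1169 and 1201. Models were built separately per library, so identifiers of unannotated models do not correspond. They were matched here by gene, chromosome, strand and the full intron chain, whatever their class. A first version that also required the same class had split such chains and was replaced after its values were seen, which lowered the number of genes with differing isoform usage. Of 70436 chains found in both libraries, 4562 carried another class in each, such as 1 with only annotated splice sites in one library and with an unannotated one in the other. Such a chain took the class with most reads. Genomic-class reads, which have no defined splicing, were left out of gene levels, and antisense and intergenic models are no part of annotated genes.

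Gene levels were counts summed over the remaining models of an annotated gene and divided by the total over such genes (CPM). Ratios are on the log2(CPM + 1) scale, library 2 over library 1. Genes with at least 10 reads summed were compared with a two-sided exact binomial test against the split of the library totals, with Benjamini-Hochberg adjustment and a threshold of 0.05. This test knows counting noise only. The coefficient of variation was estimated with edgeR 4.0.16 (common dispersion, TMM) and, as alternatives, with the trended dispersion and DESeq2 1.42.0. In data simulated with counting noise alone the exact test found 83.0% of genes changed 2-fold and called 0.06% of unchanged genes over 12378 genes. With the observed coefficient of variation added it called 13.1% of unchanged genes over 12393. A beta-binomial test at that coefficient called 0.01% and found 16% of genes changed 2-fold and 92.0% of those changed 4-fold. Changed genes were drawn from those with at least 50 reads summed, so the shares found do not cover genes with fewer. The noise was simulated at the coefficient that the beta-binomial test assumes, so the 0.01% does not test that assumption.

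The 24 gene lists of cell types, synapses, glial states, Alzheimer disease and controls were fixed before the data were examined. Their summed reads were compared by the same exact test, and the median ratio of their tested genes was placed among 10000 random lists matched on mean expression. With summed counts 23 of 24 lists passed the exact test, so the medians are reported beside it. The placement among random lists was added after the tests had been planned. Genes of a random list were drawn singly, so its range does not allow for genes that vary together. A percentile is therefore no p-value. The 4 lists of olfactory mucosa, bone marrow, bone, and muscle and liver genes were written after the gene values were seen.

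Full-length models were those classed as annotated or unannotated, without incomplete ones. Models per gene were counted in genes with at least 20 reads and models with at least 2. Shares of models and exons required 20 reads in each library. Isoform usage was tested per gene with a chi-square statistic and 10000 Monte Carlo draws, or Fisher's exact test for 2 models. In data simulated with counting noise alone it found 58.5% of genes with a 20-point shift among 1500 and called 0.46% of the others. The 0.46% is therefore no rate of false calls for these libraries, which differed by more than counting noise. An exon was tested where reads either held both junctions that include it or the junction that skips it, by Fisher's exact test. With counting noise alone simulated, this test found 17.5% of exons shifted by 20 points among 17393. Shares of single libraries carry Wilson or exact 95% intervals.

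The text names, by a rule fixed before the data were examined, the 15 most abundant nuclear genes, the 4 most abundant members of each list, every sex-check gene and every Alzheimer gene with 20 reads in each library. It also names the 8 genes with the largest ratio in each direction among those that differ with 50 reads, the 12 isoform genes with most reads, the 6 intermediate exons with most reads, the 6 genes with the smallest usage p and the 6 recurring unannotated models with most reads. Ties in the usage p were ordered by the size of the shift, a choice made after the data were seen. All tested exons of App, Mapt, Clta, Cltb, Cdc42 and Gria2 were examined, of which the text gives a part, chosen after their values were seen, over all reads that hold the exon or splice over it whatever the flanking junctions. That count was added after the data were seen. Further list members that differed were named after their values were seen. Alternatives covered the scaling, filters, pseudocounts, read classes, error model and minimum reads, and leaving out each library. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and R 4.3.3. A genome sequence was not used here, so splice site bases were not examined.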

Results

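Long-read RNA sequencing was used to profile the hippocampus of female mice heterozygous for the 5xFAD transgenes, a line that carries mutant human APP and PSEN1 genes and is used as a model of amyloid deposition in Alzheimer disease. The series held 2 libraries, which the labels number as biological replicates 1 and 2 of a single group, called library 1 and library 2 here. No wild-type, male or other comparison group was present, and the labels give no age for the animals. The design therefore supports a description of this transcriptome and of how far the 2 libraries differed, and every p-value below compares these 2 libraries and not conditions. Library 1 held 1862373 reads and library 2 held 1704633 reads, of which 335 and 302 were spike-in controls. Of these, 1751742 and 1531963 reads lay in annotated genes and entered the gene levels, given as CPM, the gene's share of such reads scaled to a sum of 1e6. A single read was worth 0.571 CPM in library 1 and 0.653 CPM in library 2, and a count of 0 allowed up to 1.71 and 1.96 CPM (3 reads). Intervals and floors cover counting error only.

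Most reads followed transcript models that are already annotated. Annotated models took 70.1% ± 3.8 of reads (SD, n = 2), with 72.8% in library 1 and 67.5% in library 2. Models that match only part of an annotated intron chain, called incomplete here, took 10.3% ± 0.62. Unannotated models that join annotated splice sites in another combination took 7.45% ± 0.211, and those with at least 1 unannotated splice site took 4.09% ± 0.02. Reads antisense to a gene took 2.40% in library 1 and 4.46% in library 2. Reads called genomic, which overlap a gene without following its splicing, took 3.22% and 5.16%, and intergenic reads took 0.270% and 0.444%. The exact 95% binomial intervals of the annotated share, 72.8% to 72.9% and 67.4% to 67.5%, did not overlap, nor did those of the antisense share, 2.38% to 2.43% and 4.43% to 4.49%.

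Among nuclear genes, Hspa8, a constitutive chaperone (chromosome 9, 40800984 to 40810087, mm10), was first with 11912 CPM ± 1906 (SD, n = 2). Ctsd, the lysosomal protease cathepsin D, followed with 9013 CPM ± 1661, and Apoe, the main lipid carrier of the brain, with 7895 CPM ± 65.0. The translation factors Eef2 and Eef1a1 stood at 6938 CPM ± 516 and 4607 CPM ± 615. Cpe, a neuropeptide-processing carboxypeptidase, had 5837 CPM ± 2058, the myelin gene Mbp 5297 CPM ± 178, the creatine kinase gene Ckb 5244 CPM ± 378 and the astrocyte filament gene Gfap 4699 CPM ± 1136. Actg1, Pkm, Fth1, Tuba1a, Ndrg4 and Sparcl1 completed the 15 most abundant genes, with 4491, 4078, 3915, 3783, 3751 and 3617 CPM. Together these 15 genes took 8.33% of gene reads in library 1 and 8.68% in library 2, and the 18 mitochondrially encoded genes took 0.0295% and 0.0376%. At least 1 read was found for 16904 genes in library 1 and 17638 in library 2, and for 15346 in both. Of the genes detected, 14381 and 14715 were protein-coding. With at least 5 reads required, 12403 and 12545 genes remained.

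Marker genes of CA1 and CA3 pyramidal neurons and of dentate granule neurons were detected. CA3 pyramidal genes summed to 301 CPM in library 1 and 180 CPM in library 2. Of 7 tested members 4 were lower in library 2 by the exact binomial test and none was higher: Bok (97.0 and 52.2 CPM), Grik4 (64.5 and 33.3 CPM), Cpne4 (42.2 and 17.0 CPM) and Elavl2 (73.6 and 47.0 CPM). The CA3 median of -0.88 in log2 ratio (library 2 over library 1) lay below that of every one of 10000 random lists matched on expression. Dentate granule genes summed to 1030 and 808 CPM, with 1 of 10 tested members lower, C1ql2 (403 and 243 CPM), Calb1 at 350 CPM ± 1.28, Stxbp6 at 96.5 CPM ± 13.7, Trpc6 at 53.5 CPM ± 9.15, and a list median of -0.48 at percentile 0.03. CA1 pyramidal genes summed to 678 and 813 CPM. Of 6 tested CA1 members 2 were higher, Wfs1 (287 and 357 CPM) and Mpped1 (285 and 354 CPM), while Fibcd1 had 90.8 and 82.2 CPM and Zdhhc23 14 and 10 reads, and the list median of 0.31 lay inside the range of the random lists. Adjusted over the list alone, 4 CA3, 2 dentate and 2 CA1 genes were called. None of these calls passed a beta-binomial test that allows for the coefficient of variation observed between the libraries (0.172, estimated with edgeR), and with genomic-class reads added Wfs1 and Grik4 no longer passed the exact test (adjusted p = 0.088 and 0.057).

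General excitatory neuron genes summed to 2998 CPM ± 327 (SD, n = 2). Camk2a, a synaptic kinase, was higher in library 2 (408 and 589 CPM), as was Grin2a (17 and 43 reads). Chn1 (2427 and 1786 CPM) and Neurod6 (138 and 81.6 CPM) were lower, and Arpp21 had 199 CPM ± 26.5. The list's sum was lower in library 2 by 0.22 in log2 while its member median was higher by 0.27, so the list had no single direction. Of its 9 tested members 2 were higher and 2 lower. Inhibitory neuron genes summed to 940 and 749 CPM, with Gad1, the GABA-synthesising enzyme, at 627 and 490 CPM and the neuropeptide gene Cck at 62.2 and 28.1 CPM among 2 of 13 tested members that were lower. Erbb4 (1 and 10 reads) was higher, Gad2 had 103 CPM ± 12.7 and Adarb2 29.3 CPM ± 1.05. Presynaptic genes summed to 7285 CPM ± 736, with 6 of 16 lower and 2 higher (3 lower and 3 higher with genomic-class reads added), among the lower Snap25 (2542 and 2215 CPM) and Syp (1895 and 1322 CPM), and with Cplx1 at 816 CPM ± 53.9 and Stxbp1 at 651 CPM ± 12. Postsynaptic genes summed to 4354 CPM ± 556, with 4 of 11 lower, the glutamate receptor genes Gria1 (1291 and 1044 CPM) and Gria2 (1170 and 990 CPM), Camk2b (1169 and 965 CPM) and Dlgap1 (741 and 604 CPM), and 1 higher, Grin2b (31 and 71 reads), which with genomic-class reads added was no longer called. Neither synaptic list had a median outside the range of random lists (percentiles 13 and 3.93). Immediate early genes summed to 450 CPM ± 65.9, with Junb at 220 CPM ± 19.7, Arc at 78.1 CPM ± 9.83, Dusp1 at 42.3 CPM ± 0.734 and Ier2 at 36.7 CPM ± 3.85. Egr1 alone of 8 tested members differed (66 and 1 reads), a difference in part due to the class of its reads. Genes of neighbouring brain regions summed to 248 CPM ± 44.6, beside 240 CPM ± 86.2 for the CA3 list. Prkcd had 73.8 CPM ± 14.7, Ppp1r1b 66.3 CPM ± 11.4, Rgs9 21.5 CPM ± 3.57 and Cux2 19.3 CPM ± 8.72. Adjusted over the list alone, 6 excitatory, 3 inhibitory, 11 presynaptic, 6 postsynaptic and 1 immediate early genes were called. No excitatory, inhibitory or postsynaptic gene passed the beta-binomial test at the observed coefficient of variation.

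By the exact test, which knows counting noise only, astrocyte and microglia genes were higher in library 2 and oligodendrocyte genes were lower. Of 13 astrocyte genes 10 were higher (8 with genomic-class reads added) and none was lower, with the list at 13362 and 18328 CPM. Gfap had 3896 and 5503 CPM, Aldoc 2721 and 3856 CPM, Sparcl1 3103 and 4131 CPM and the glutamate transporter gene Slc1a3 1477 and 2002 CPM. Of 14 homeostatic microglia genes 6 were higher and none was lower, at 4239 and 5644 CPM in sum. Hexb had 2173 and 2871 CPM, the receptor gene Csf1r 546 and 922 CPM, Fcrls 337 and 447 CPM and Cx3cr1 182 and 287 CPM. Of 15 oligodendrocyte genes 7 were lower and none was higher, at 13663 and 12207 CPM, with Plp1 at 1657 and 1313 CPM, Trf at 3561 and 3162 CPM, Cnp at 1368 and 1218 CPM and Mbp at 5423 and 5172 CPM. Adjusted over the list alone, 11 astrocyte, 6 microglia and 9 oligodendrocyte genes were called. No gene of these 3 lists passed the beta-binomial test at the observed coefficient of variation. The astrocyte and microglia medians of 0.44 and 0.33 exceeded those of all 10000 random lists, and the oligodendrocyte median of -0.25 lay at percentile 0.87. Oligodendrocyte precursor genes summed to 381 CPM ± 54.5, with 1 of 7 higher, Gpr17 (25.1 and 47.7 CPM), Olig1 at 194 CPM ± 16.7, Olig2 at 73.4 CPM ± 12.5 and Pdgfra at 39.1 CPM ± 8.44. Endothelial genes summed to 898 CPM ± 149, with 3 of 9 higher (2 with genomic-class reads added), Slco1a4 (175 and 235 CPM), Itm2a (159 and 203 CPM) and Flt1 (55.9 and 96.6 CPM), Cldn5 at 254 CPM ± 22.7 and Pecam1 at 87.2 CPM ± 14.3. Adjusted over the list alone, 1 precursor and 3 endothelial genes were called, and the endothelial median of 0.35 lay at percentile 98.7. None of the precursor and endothelial genes passed the beta-binomial test.

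Genes of disease-associated microglia, the state that surrounds amyloid plaques, were abundant in both libraries at 25851 CPM ± 1969 (SD, n = 2), most of it from Ctsd, Apoe, Fth1 and Ctsb (2773 and 3632 CPM), which other cells also express. Of 23 tested members 5 were higher in library 2 and 3 were lower by the exact test, and the median of 0.08 lay inside the range of random lists. Trem2, the microglial lipid receptor, had 85.1 CPM ± 3.32, Itgax 56.2 CPM ± 16.5, Cst7 36.0 CPM ± 11.2 and Clec7a 27.3 CPM ± 4.74. Spp1 (250 and 118 CPM) and Gpnmb (48.5 and 25.5 CPM) were among the lower members. Complement genes summed to 851 CPM ± 81.4, with C4b (243 and 303 CPM) and Cfh (32.0 and 83.6 CPM) higher among 7 tested, and C1qa at 206 CPM ± 17.1, C1qb at 162 CPM ± 2.77 and C1qc at 104 CPM ± 13.2. Interferon response genes summed to 668 and 462 CPM. Their median of -0.48 lay at percentile 0.05, although only Ifit3 (304 and 188 CPM) of 7 tested members passed the test on its own, with Stat1 at 125 and 103 CPM, Ifit1 at 69.1 and 50.9 CPM and Oasl2 at 57.2 CPM ± 13.5. The counts called adjusted over the list alone were 10 disease-associated, 2 complement and 1 interferon genes. In the beta-binomial test no gene of these 3 lists was called. With DESeq2 size factors the complement list as a whole no longer passed the test.

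**Figure D1:**
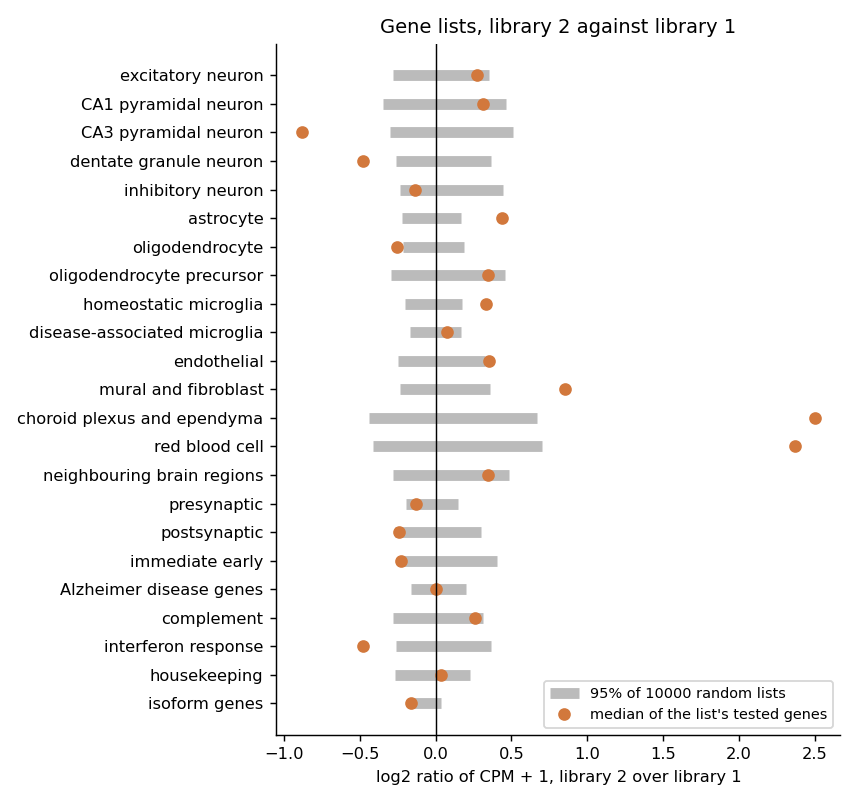
Median log2 ratio of CPM + 1, library 2 over library 1, of the tested genes of each list (points), with the range that holds 95% of the medians of 10000 random gene lists of the same size and expression (grey bars). CA3 (-0.88), dentate, interferon, oligodendrocyte and isoform lists lie left of their grey bars, and astrocyte (0.44), homeostatic microglia, endothelial, mural, choroid plexus and red blood cell lists lie right of theirs.

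Among 25 genes linked to Alzheimer disease, 6 differed between the libraries by the exact test and 0 by the beta-binomial test at the observed coefficient of variation, and the summed level of 14056 CPM ± 428 was nearly equal, lower in library 2 by 0.06 in log2 with a member median of 0.00. App (chromosome 16, 84949685 to 85173766, minus strand) had 1752 CPM ± 191, Psen1 97.3 CPM ± 2.75 and Prnp 1808 CPM ± 128. The reference annotation is of the mouse, so reads of the human APP and PSEN1 transgenes that align to the mouse genes cannot be separated from mouse transcripts in these values. Clu, which encodes clusterin, had 774 CPM ± 110 and was higher in library 2, as was Ncstn, a gamma-secretase subunit gene, at 73.6 and 109 CPM. App, Prnp, Ptk2b (415 and 281 CPM) and Snca (156 and 84.9 CPM) were lower. Bin1 had 439 CPM ± 26.5, Bace1 205 CPM ± 22.4, Mapt 122 CPM ± 20.3, Sorl1 114 CPM ± 10.4, Fermt2 48.8 CPM ± 7.63, Plcg2 31.0 CPM ± 4.22, Adam10 28.0 CPM ± 0.0682, Inpp5d 16.7 CPM ± 5.02, Thy1 14.5 CPM ± 2.07, Aph1a 13.4 CPM ± 0.456 and Picalm 12.2 CPM ± 1.16, none of which passed the test. With genomic-class reads added, Thy1 went from 28 and 20 to 102 and 72 reads and Picalm from 20 and 20 to 41 and 47. Adjusted over the list alone, 6 genes were called. Housekeeping genes summed to 11332 CPM ± 251, with Actb at 990 CPM ± 94.2 and Pgk1 at 708 CPM ± 108, while Gapdh had 16 and 19 reads. Of 10 tested members 2 were higher (Eef1a1 and Actb) and 3 were lower (Pgk1, Ubc and Ppia), and 5 were called adjusted over the list alone. The list's summed ratio of 0.05 in log2 turned to -0.02 with TMM scaling, where the list no longer passed the test, and to -0.06 with DESeq2 size factors. No read of the Y-linked genes of the sex check was found, and Xist had 1 and 0 reads in the classes counted here.

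Choroid plexus and blood genes were higher in library 2, as were 2 collagen genes of the mural and fibroblast list. That list stood at 327 CPM in library 1 and 1700 CPM in library 2, or 313 and 467 CPM without these 2 genes, both also on a list of bone genes, with 5 of 9 tested members higher, led by the collagen genes Col1a1 (21 and 1766 reads) and Col1a2 (3 and 124 reads), and including Dcn (35.4 and 64.6 CPM), whereas the pericyte genes Rgs5 (144 and 213 CPM) and Vtn (71.4 and 86.2 CPM) differed less. Choroid plexus and ependyma genes had 400 and 886 CPM, with 4 of 5 tested members higher, including the transthyretin gene Ttr (18.8 and 136 CPM) and Enpp2 (375 and 712 CPM), and Prlr (2 and 17 reads), with Kl at 8 and 16 reads. Of 5 red blood cell genes 3 were higher, Hba-a1 (10.3 and 57.4 CPM), Hba-a2 (4.57 and 36.6 CPM) and Hbb-bs (4.57 and 31.3 CPM), while Alas2 had 9.71 and 13.1 CPM. Hba-a1 and Hba-a2 are near-identical copies of one type of globin gene, so the split between them is uncertain. Of these lists, adjusted over the list alone, 5 mural and fibroblast, 4 choroid plexus and 4 red blood cell genes were called. At the observed coefficient of variation 2 mural, 2 choroid plexus and 3 red blood cell genes were called. Of the other lists, the presynaptic list had 1 call in each direction (Bsn and Cplx2) and the immediate early list 1 (Egr1), and none of these 3 passed that test with genomic-class reads added. The isoform list, chosen for known splicing and not for a cell type, summed to 51688 and 49794 CPM, with 7 of 52 tested members higher, 19 lower, 33 called adjusted over the list alone and a median of -0.16 at percentile 1.38.

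Across 19196 genes with a read in either library, log2(CPM + 1) values correlated with Pearson r = 0.961 and Spearman rho = 0.941. This correlation runs across genes, which are not independent replicates. The common biological coefficient of variation, estimated with edgeR over genes with at least 10 reads summed, was 0.172. The libraries differed by more than counting noise, and the coefficient cannot separate animals from the handling of each library.

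**Figure D2:**
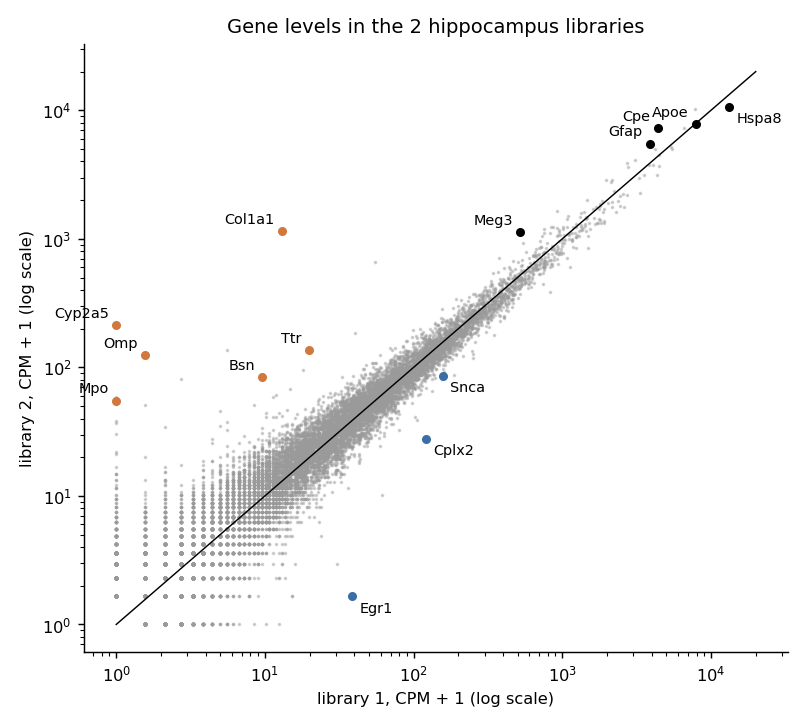
Level of each gene in library 1 (horizontal axis) and library 2 (vertical axis), in CPM + 1 on log scales, with the line of equal levels. Small grey points are all genes, and named points are orange if higher, blue if lower and black if among abundant genes; off the line are Col1a1, Cyp2a5, Omp and Mpo, found mainly in library 2, and Egr1 and Cplx2, lower there.

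Of 12416 genes tested with the exact binomial test and Benjamini-Hochberg adjustment, 1224 differed between the libraries, 703 higher and 521 lower in library 2. The split of calls depended on the scaling, with 560 higher and 724 lower with TMM-scaled totals and 480 higher and 882 lower with DESeq2 size factors, which shift all log2 ratios by -0.06 and -0.10. When the test allowed for the observed coefficient of variation (a beta-binomial test chosen after the data were seen), 62 genes remained, 54 higher and 8 lower. The 8 genes with the largest ratios in library 2 were Cyp2a5, a cytochrome P450 of liver and nasal epithelium, with 0 and 327 reads (at least 125-fold higher against a floor of 3 reads per library), Col1a1, Omp, the marker of mature olfactory neurons, with 1 and 189 reads, the neutrophil granule genes Ltf (0 and 89 reads, at least 33.9-fold) and Mpo (0 and 83 reads, at least 31.6-fold), Cyp2g1 (0 and 78 reads, at least 29.7-fold), Gm15319 (0 and 57 reads, at least 21.7-fold) and Stoml3, of olfactory cilia, with 0 and 55 reads (at least 21-fold). The adjusted p of these 8 genes in the beta-binomial test was at most 1.8e-09, as for Stoml3.

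The 8 genes with the largest ratios in the other direction were Egr1 (66 and 1 reads), Mpeg1 (52 and 3), Adcy1 (106 and 14), Cplx2 (212 and 41), Wipf3 (62 and 16), Gm20186 (40 and 11), Cwc15 (39 and 11) and Ece2 (184 and 58). At the observed coefficient of variation the last 4 no longer passed, with a beta-binomial adjusted p of 0.15 for Wipf3, 0.48 for Gm20186, 0.54 for Cwc15 and 0.083 for Ece2. With genomic-class reads added, Egr1 had 66 and 30 reads, Mpeg1 52 and 83, Adcy1 213 and 229, Cplx2 213 and 196, Wipf3 66 and 52 and Gm20186 40 and 57. Cwc15 then had 39 and 13 and Ece2 186 and 58. The presynaptic gene Bsn showed the converse, with 15 and 127 reads that became 107 and 135. Of the genes called with the observed coefficient of variation, 41 of 54 higher and 2 of 8 lower ones were also called with genomic-class reads added.

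Genes with at least 20 reads expressed 3.92 ± 0.0155 full-length models each (SD, n = 2), counting annotated and unannotated models with at least 2 reads, and 77.6% of 8559 genes in library 1 and 77.3% of 8546 in library 2 had 2 or more. The most abundant model took a median of 79.0% ± 1.85 of a gene's full-length reads over 7023 genes. It was the same model in both libraries for 94.2% of genes, took over 90% of reads in 31.1% of them and under 50% in 20.4%, and was unannotated for 514 genes.

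Of 53 genes on a list of known isoform regulation, 44 had at least 50 full-length reads in each library, and their dominant share ranged from 16% to 99.0%, with a median of 64%. Apoe-206 took 97.8% ± 0.0714 of Apoe reads (SD, n = 2) and Prnp-201 99.0% ± 0.148 of Prnp reads. App-201, with 16 exons, took 89.5% ± 2.33 of App reads. Gfap-201 took 88.4% ± 0.934, Snap25-201 83.8% ± 4.12, Mbp-211 74.5% ± 1.99 and Plp1-201 71.7% ± 0.838. Ndrg4-202 took 73.2% ± 3.73, Camk2b-209 70.5% ± 1.40, Ndrg2-202 55.7% ± 1.57 and Gria2-201 53.0% ± 4.54. For Pkm, a glycolytic enzyme gene, Pkm-202 took 83.0% in library 1 and 72.1% in library 2, and Pkm-201 14.8% and 25.4%. Among all 44 genes 7 had a share over 90% and 9 a share under 50%.

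**Figure D3:**
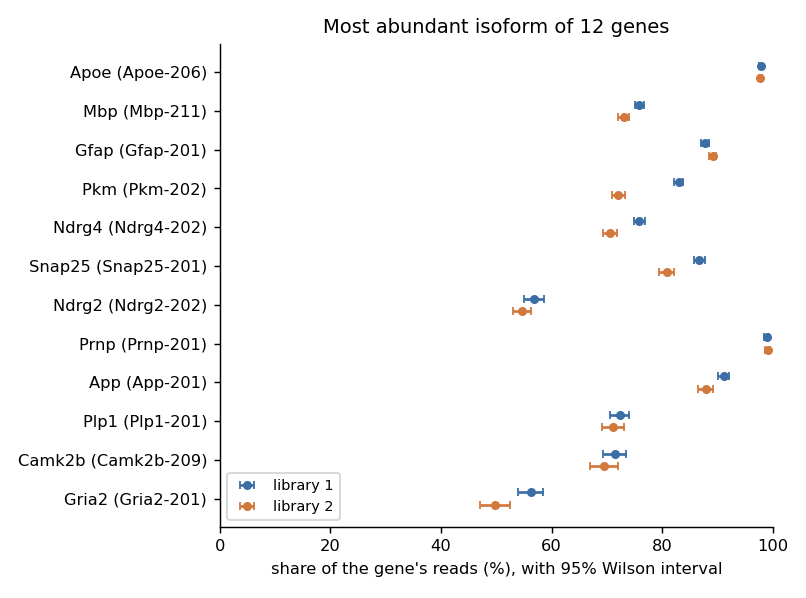
Share of each gene's full-length reads in its most abundant model, in library 1 and library 2, with 95% Wilson intervals (counting error only), for the 12 listed genes with most reads. Shares run from 53.0% for Gria2 to 99.0% for Prnp, and the intervals of the 2 libraries do not overlap for Mbp, Pkm, Ndrg4, Snap25, App and Gria2.

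Isoform usage was compared per gene. A Monte Carlo permutation test with 10000 draws, which knows counting noise only, called 109 of 6805 genes, 1.6% of them. The 6 genes with the smallest p (0.0001, the smallest the draws can give, adjusted p = 0.01) and the largest shift were Gm45837, Tmppe, Pakap, Rffl, Plppr2 and Ssu72. In Ssu72, a phosphatase gene of RNA polymerase II (chromosome 4), Ssu72-201 took 84.6% of reads in library 1 and 40.7% in library 2, and Ssu72-203 took 15.4% and 51.9%. In Plppr2 the annotated Plppr2-201 took 97.6% and 52.8%, and an unannotated model with 0 and 71 reads took 0% and 44.1%. In Tmppe the annotated model held 20 of 20 reads and 8 of 39. In Pakap and Rffl, single unannotated models with 15 and 19 reads in library 1 had none in library 2. Gm45837 overlaps Pde2a on the same strand, and while Gm45837 had 94 and 1012 reads in all, Pde2a had 1439 and 589, so the division of reads between them is uncertain. With annotated models only, the same permutation test kept Ssu72 (adjusted p = 0.012) and lost Plppr2 (adjusted p = 1), and the other 4 genes had no test there.

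Cassette exon inclusion was measured among reads with a given pair of flanking junctions. An exon was counted once for each such pair, and other exon ends made another exon. The same exon can therefore be counted more than once and at unlike inclusion. Of 17393 exons counted in this way with at least 20 informative reads in each library, 1163 in 884 genes had a mean inclusion of 20% to 80%. A further 6973 lay under 5% and 7148 over 95%. The intermediate exons differed between the libraries by a median of 6.81 percentage points. By Fisher's exact test 11 exons differed. This test, which knows counting noise only, found 17.5% of simulated shifts of 20 points. The intermediate exons with most reads were a 54-nucleotide coding exon of Rapgef4 (chromosome 2, 72174423 to 72174476), included in 39.5% and 45.9% of reads, and a 186-nucleotide coding exon of Pja2 (chromosome 17, 64297724 to 64297909) at 27.8% ± 0.719 (SD, n = 2). They were followed by a 60-nucleotide coding exon of Eif4h (chromosome 5, 134624441 to 134624500) at 65.2% ± 1.6, a 59-nucleotide untranslated exon of Hmgcs1 (chromosome 13, 119694989 to 119695047) at 43.7% ± 0.463 and a 51-nucleotide coding exon of Klc1 (chromosome 12, 111793649 to 111793699) at 29.2% ± 1.74, or 37.3% ± 0.0623 over all reads that hold it or splice over it. A 91-nucleotide coding exon of Gpm6b (chromosome X, 166385391 to 166385481) was included in 19.9% and 35.2% of reads, a difference that passed Fisher's exact test (adjusted p = 3.1e-11), as did the difference for Rapgef4 (adjusted p = 0.04).

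Tested exons of App, Mapt, Clta, Cltb, Cdc42 and Gria2 were examined whatever their inclusion, and their shares are given over all reads that hold the exon or splice over it. In App, the 168-nucleotide exon that encodes the Kunitz protease inhibitor domain (chromosome 16, 85043576 to 85043743) was included in 5.81% of reads in library 1 and 8.99% in library 2. The 57-nucleotide exon beside it, at 85040251 to 85040307, was included in 2.56% and 4.78%. Fisher's exact test over all reads gave an unadjusted p of 5.5e-06 for the Kunitz exon and 1e-05 for the 57-nucleotide exon. With given flanking junctions no App exon differed after adjustment. The 54-nucleotide exon at 84971408 to 84971461 was included in 96.4% ± 0.762 (SD, n = 2). Reads of the human APP transgene cannot be separated here either. In Mapt, the 93-nucleotide exon (chromosome 11, 104318157 to 104318249) that encodes a microtubule-binding repeat was skipped in 1 of 214 reads in library 1 and 0 of 157 in library 2. An 87-nucleotide Mapt exon at 104287123 to 104287209 was included in 25.2% ± 0.146, one at 104289908 to 104289994 in 13.1% ± 1.24, and a 759-nucleotide exon at 104298498 to 104299256 in 6.05% ± 0.121. In Clta, the clathrin light chain gene, the 54-nucleotide exon at 44030215 to 44030268 on chromosome 4 was included in 66.0% ± 5.75 of reads and the 36-nucleotide exon at 44031400 to 44031435 in 64.8% ± 6.06. Among reads with the latter exon the former was included in 90.5% ± 2.04, and among those without it in 21.6% ± 8.42. The 54-nucleotide exon of Cltb (chromosome 13, 54597026 to 54597079) was included in 70.6% and 47.9% of reads with its main flanking junctions (Fisher's exact test, adjusted p = 0.012). In Gria2, a pair of mutually exclusive 115-nucleotide exons on chromosome 3 shared the reads, with 33.5% ± 1.01 using the exon at 80690404 to 80690518 and the rest the exon at 80691320 to 80691434. All 6 tested Cdc42 exons, some of which overlap, were unannotated and under 5% included. The exon test covers internal exons and cannot show a choice between last exons. Cdc42-202 and Cdc42-201, which end at different positions, took 63.2% and 32.5% of full-length reads in library 1 and 73.3% and 22.1% in library 2.

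Unannotated spliced models recurred less often than annotated ones. Of annotated multi-exon models, 83.3% of those in library 1 were found in library 2 and 80.3% of those in library 2 in library 1. Of unannotated full-length models, matched by their whole intron chain, 30.9% and 30.3% recurred, which covered 68.7% and 65.8% of the reads in such models. Of 25907 recurring chains, 4040 had at least 5 reads in each library. With at least 5 reads required in each library, the gap was smaller. A mean of 89.8% of annotated models then recurred. The mean was 71.2% for unannotated models that join annotated splice sites and 63.9% for those with an unannotated site. Of the 6 unannotated models with most reads, 5 held over 50% of their gene's full-length reads. A 14-exon model of Apbb1, an adaptor of the APP protein (chromosome 7, 105558483 to 105581192), had 1440 and 1036 reads and took 60.2% ± 3.0 of its gene's full-length reads (SD, n = 2). A 5-exon model of the ornithine decarboxylase antizyme gene Oaz2 (chromosome 9, 65676548 to 65690300) took 93.9% ± 0.697. A 14-exon model of the dynactin gene Dctn2 (chromosome 10, 127266368 to 127281950) took 82.6% and 77.4% and a 6-exon model of Chmp1a (chromosome 8, 123204264 to 123212760) 91.3% ± 1.56. In Rapgef4, 2 models that differ by the 54-nucleotide exon took 53.2% ± 4.35 and 38.9% ± 3.57.

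The share of incomplete models grew with transcript length above 1 kb. It was 4.99% ± 0.879 (SD, n = 2) in genes whose longest expressed model measured 1 to 2 kb, 7.66% ± 0.571 at 2 to 3 kb, 12.9% ± 1.17 at 3 to 4 kb, 18.8% ± 1.28 at 4 to 6 kb and 30.5% ± 2.26 above 6 kb. Under 1 kb it was 14.1% ± 2.23. Each bin was higher in library 2. Of incomplete reads, 55.8% and 52.3% were classed as keeping only the 3′ end of an annotated transcript and 32.2% and 35.9% only its 5′ end. A further 3.17% and 3.53% were classed as both. Spike-ins took 0.018% and 0.0177% of reads and covered 19 control genes, whose reads correlated between libraries with Pearson r = 0.916. All 101 and 93 ERCC reads were in annotated models, but these controls are unspliced and cannot test the calling of unannotated splicing. Of 234 and 209 SIRV reads only 19 and 12 were, and 117 and 102 were in models called unannotated. The exact 95% intervals of the unannotated shares are 43.4% to 56.6% and 41.8% to 55.8%. How far such calls enter the unannotated shares of mouse genes was not tested.

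**Figure D4:**
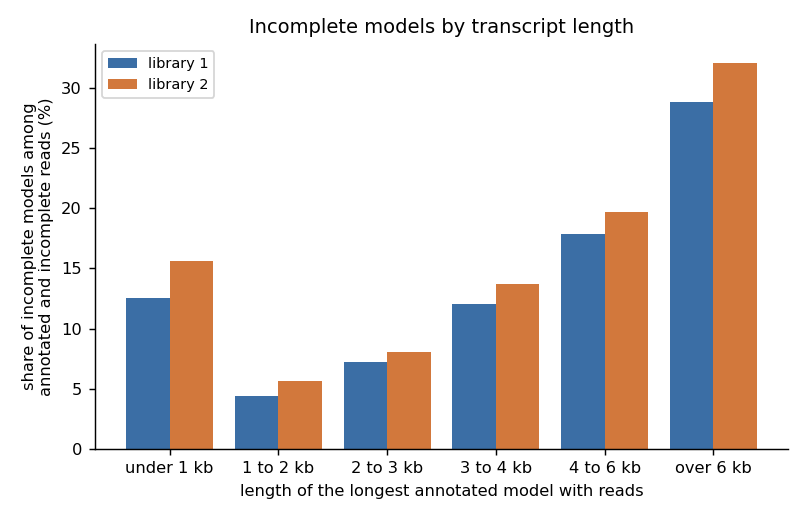
Share of incomplete models among annotated and incomplete reads (vertical axis, in percent) by the length of the gene's longest annotated model with reads (horizontal axis), in library 1 and library 2. The share goes from 4.99% at 1 to 2 kb to 30.5% above 6 kb as a mean of the 2 libraries.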

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

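Signals in 3 kinds of reads outside the gene levels of the report exceeded the limit that a count of 0 allows. For the patterns below, the olfactory receptor test was set before its counts were seen. The bone and marrow, wrong gene, other library, length, neuron share, subfield, locus and splicing tests were chosen after the result, or values related to it, had been seen.

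Genomic-class reads of Xist, the noncoding RNA of the inactive X chromosome, numbered 29 in library 1 and 37 in library 2, while its other classes held 1 and 0. Antisense reads piled up at chromosome 17, 39843013 to 39846245, on the minus strand against Gm26917, with 1298 and 1729 reads and no spliced read. A spliced intergenic locus at chromosome 5, 30223095 to 30229889, minus strand, had 23 and 24 reads and overlaps no annotated gene.

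The first pattern is the presence of olfactory, bone and marrow transcripts in library 2. Olfactory receptor genes, a family not examined before, had reads for 8 genes in library 1 and 66 in library 2, a ratio of 8.25. By the bound set for the test, this makes RNA of olfactory mucosa in library 2 a candidate explanation. These genes held only 24 and 94 reads in all. Library 2 also had more reads that follow no annotated splicing, and their part in this count was not tested. Of the bone and marrow list members with at least 10 reads, 100% had a higher CPM in library 2, whether or not they passed the test, but these lists were written after their main genes had been seen, so this decides nothing. Reads given to a wrong gene stay open. The test counts only annotated spliced models, so correct reads of a gene without introns would count as misplaced. Of the library 2 reads of the 24 raised members, 77.4% were in such models, between the bounds of 50% and 80% set for the test. The test was for a time redefined, after that value was seen, as the share of members with most reads in such models (20 of 24, 83.3%), which would have argued against the explanation, and the first definition was kept. The lists held 0.236% of library 2 reads, and reads of another sequencing library cannot be told apart, because the files hold no index or run information.

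The second pattern is the shift between cell type lists. A length bias as the whole cause is argued against, since with the median of genes of like length taken off, 100.4% of the gap of 0.856 in log2 was left between the glial lists and the CA3, dentate and oligodendrocyte lists, over members with a length. A lower share of neurons alone would raise oligodendrocyte genes, whose median of -0.254 lay below the random range of -0.215 to 0.191. This argues against it for the oligodendrocyte genes only. Their low median was part of the pattern that prompted the test, so the result is no independent support. The CA1 median exceeded the CA3 median by 1.2, against a random range of -0.653 to 0.522, but the low CA3 median had prompted the test and the CA1 median of 0.314 lay inside its own random range, so this decides nothing. Another share of hippocampal subfields stays open, as does the astrocyte and microglia shift, and a difference between the animals was not tested.

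The third pattern is the larger share of antisense, intergenic and genomic-class reads in library 2, 10.1% against 5.89%. The 10 loci of 10 kb with most such reads gave 1.47% of the difference, which argues against a few loci. Antisense and intergenic reads of 1 exon were 1.85-fold higher and spliced ones 1.41-fold higher, a ratio of 1.32. For these classes more unspliced RNA or DNA in library 2 stays a candidate, although the spliced reads were higher as well. Genomic-class reads, 3.22% and 5.16% of reads, were not part of this test. Adding them took Cplx2 from 212 and 41 reads to 213 and 196, and Bsn from 15 and 127 to 107 and 135. How far such shifts of class make up the difference was not tested. Apart from the tests of tissue composition above, no biological explanation was tested for the 3 patterns, since the series has 1 group.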

How the results depend on the processing

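Leaving out either library replaces a mean by the value of the other, which with 2 libraries always lies within 1 SD, so it says nothing about stability, and comparisons between the libraries cannot be made without one. No paired analysis was possible because there is 1 group. Settings chosen after the data were seen are the beta-binomial test at the observed coefficient of variation, genomic-class reads added to the tests of genes, the correlation and the coefficient of variation, DESeq2 size factors for lists, a 10-point minimum for usage, all reads for named exons, and leaving carry-over genes out of the total. The placement of list medians among random lists was also added after the tests had been planned. The cause of the shifts below was not tested unless named.

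With multi-exon models only, the annotated share was 76.2% and the unannotated full-length share 12.9%, which follows from leaving out single-exon antisense and genomic reads. Within known genes the latter was 12%. The correlation was 0.876 with a pseudocount of 0.1 CPM and 0.982 with 10. The coefficient of variation was 0.197 from the edgeR trend and 0.341 from the DESeq2 fit. Genes that differ numbered 158 with a beta-binomial test at 0.1, 62 at the observed coefficient of variation and 61 there with genomic-class reads. The housekeeping list ratio turned from 0.05 to -0.0174 with TMM (exact binomial test, adjusted p = 0.26) and -0.0579 with DESeq2 size factors, and the complement list lost its call with the latter (exact binomial test, adjusted p = 0.099). Models per gene were 10.9 with 1 read per model, 1.96 with 5 reads, 3.32 with unannotated models only if in both libraries and 6.22 with incomplete models. The median dominant share was 66.8% with incomplete models, 97.4% with annotated models only and 81.9% with 50 reads. Genes with differing usage numbered 62 with annotated models only, which tests fewer genes, and 418 with incomplete models. Exons of 20% to 80% numbered 369 with annotated models only and 592 with 50 reads, for fewer exons tested, and 7 differed with annotated models only. Recurring unannotated models were 53.8% with 2 reads, 69.3% with 5 reads and 31.2% with junctions within 2 bases. Recurring annotated models were 86.0% with 2 reads and 89.8% with 5 reads. The spike-in correlation was 0.711 with a pseudocount of 0.1.

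Values that leave out a library aside, the other 28 alternative values stayed within the limits set, 1.5-fold for counts and 1 SD for shares. They include 12474 genes detected with 5 reads and 1070 to 1492 genes that differ with other scalings, no filter or genomic-class reads. The remaining values cover single genes, lists, models, exons, the antisense and genomic shares and the numbers of genes higher or lower in library 2. Of these, 805 stayed and 101 moved. Without 1 library, annotated reads ranged from 67.5% to 72.8%, genes detected from 16904 to 17638 and incomplete models above 6 kb from 28.9% to 32.1%. The isoform usage test found 58.5% of 20-point shifts simulated with counting noise alone, and 95.1% in genes with at least 100 reads in each library.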

Other observations

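Long noncoding genes added a further group. Meg3, an imprinted noncoding gene of neurons, had the highest mean of the 2 libraries, with 521 CPM in library 1 and 1125 CPM in library 2. The next was 2900097C17Rik, which was above it in library 1, with 771 CPM ± 33.8 (SD, n = 2). Malat1, a nuclear-retained transcript, had 147 and 187 CPM. At least 1 read was found for 1463 and 1420 long noncoding genes, 948 of them in both libraries. These genes were chosen after their values were seen.

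Some glycolytic genes were looked at beside Gapdh. Aldoa had 2183 CPM ± 598 (SD, n = 2), Eno1 1969 CPM ± 274, Gpi1 1968 CPM ± 101, Pgam1 1158 CPM ± 133 and Tpi1 1021 CPM ± 219, whereas Gapdh had 10.8 CPM ± 2.31 and no genomic-class reads beyond these. The cause of the low Gapdh count was not tested, so it need not reflect the level of the transcript. Nrgn, a postsynaptic gene of excitatory neurons, had 5 and 8 reads, or 41 and 27 with genomic-class reads. These genes were also chosen after their values were seen.

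The exon with the smallest p between the libraries lay in Enpp2, at chromosome 15, 54851348 to 54851422, 75 nucleotides, coding. It was included in 39.3% of 623 reads in library 1 and 19.9% of 1035 in library 2 (Fisher's exact test, adjusted p = 3.3e-13), and the level of Enpp2 differed as well. The largest shift was in Eif4g1 (31 of 34 and 11 of 40 reads). Others that differed were in Rpn2 (49.7% and 34.3%), Asph (62.5% and 48.3%), Car12 (0 of 91 and 18 of 69 reads), Ndrg4 (94.0% and 90.3%), AC149090.1 (48.4% and 70.4%) and Atp6v1h (15.5% and 25.3%), besides Gpm6b, Cltb and Rapgef4 in the report.

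The lists written after the values were seen gave these sums. Olfactory mucosa genes had 139 CPM in library 1 and 811 CPM in library 2, with 14 of 17 members with 10 reads higher and none lower. Marrow myeloid genes had 4.57 and 193 CPM with 5 of 5 higher, and bone genes 61.1 and 1360 CPM with 5 of 7 higher, of which Col1a1 and Col1a2 also belong to the mural and fibroblast list. Skeletal muscle and liver genes had 18 and 4 reads, and the 1 member with 10 reads did not pass the test. In library 1, 9 olfactory, 2 marrow and 7 bone genes also had reads.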
